A study of Mus musculus with 48 samples.

How the data were processed

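The series holds 48 small RNA libraries from CD1 mouse ovaries at embryonic day 13.5. Per the labels, pregnant females were exposed through the drinking water for the first 13 days of pregnancy, mesonephros was removed, and germ cells were taken from pools of about 80 gonads with anti-CD15 paramagnetic beads. RNA under 100 bases, from samples with a RIN of at least 8, was sequenced from libraries made from more than 1 µg of RNA. Per the labels, the generation number, exposure, fraction and replicate number of each library are given by its title, and all 48 could be placed.

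The authors deposited 1 table of whole-number read counts for 563 mature miRNAs, each summed over the canonical form and its isomiRs per the file headers. Per the submitters' processing notes Bowtie 1.3.1 and the genome build mm39 were used; the miRNA annotation and counting rules are not given in the sources used here. The table leaves 7089 of its 27024 cells blank (26.2%) and lists no 0. The smallest listed count averaged 140 in PGC and 135 in SC libraries, or 24.1 and 13.6 CPM. The rule behind the blanks is not given in the sources used here. Where 1 library of a group was blank, the listed value of the other had a median of 1.37 times the smallest listed value of its own library and a 90th percentile of 3.99 times, so a blank was read neither as 0 nor as surely under a limit. Reads of blank cells are missing from the totals, which therefore are totals of listed counts and not sequencing depth. PCR reads without molecular identifiers are not independent molecules. piRNAs were not analysed here. No coordinates are given, since the reference genome at hand is of another build.

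The design had been set for a complete count table. Because of the blanks, each fit used the miRNAs listed in every library of that fit: 251 for all 48 libraries, 303 for the 24 PGC and 355 for the 24 SC libraries. In their own fraction's libraries these held on average 99.4% and 99.5% of listed counts. This leaves out miRNAs left blank in some libraries; alternatives with blanks as 0 and at the smallest listed count cover them.

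Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, robust quasi-likelihood fit, two-sided test), with Benjamini-Hochberg adjustment over the miRNAs of a comparison and calls at an adjusted p under 0.05. The biological coefficient of variation was 0.310 over all libraries, 0.336 in PGC and 0.297 in SC. The comparison of fractions used all 24 groups in 1 fit and contrasted the mean of the 4 control PGC groups with that of the 4 control SC groups. Exposure comparisons used the 12 groups of a fraction in 1 fit, with 12 residual degrees of freedom: each disruptor against control as a mean over F1, F2, F2Sy and F3, each disruptor against control in each class (16 comparisons), the joint test of differences between classes, F2Sy against F2, MEHP against VZN, and the controls between classes. The difference of mean effects between fractions used all 48 libraries. CPM are counts scaled by the listed total of a library, and log2 CPM add a prior count of 2.

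The names given follow a rule set before the data were examined, as were the main tests, the lists and most alternatives. For the fractions and the mean effects they are the 10 miRNAs per direction with the largest fold change among calls with at least 10 CPM and the same sign in all 4 classes, and within a class the 3 per direction whose 2 exposed and 2 control libraries do not overlap. Where nothing passed, the 2 miRNAs with the smallest p are given as values, and up to 4 members of each list with the highest mean CPM serve as examples. miRNAs outside this rule (miR-25-3p, miR-140-5p and those listed in 1 fraction only) were named after their values were seen.

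The 21 lists cover germ cell and pluripotency clusters (miR-290-295, miR-302-367, X-linked, Sfmbt2, miR-183), miR-17-92, let-7, Dlk1-Dio3, miR-15/16, miR-29, miR-200, miR-21 with miR-23b, p53-responsive miRNAs, and markers of mesenchymal, erythroid, leukocyte, endothelial, muscle, neural and liver cells and of hypoxia. Lists with at least 4 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. fry asks only whether the members move one way. For the fractions and mean effects the mean log2 CPM of every list with a tested member was also compared by an exact permutation of group labels within generation classes (1296 arrangements, two-sided, smallest p 0.00154), which was added after the data were seen. Correlations across libraries used 100000 permutations.

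Alternatives were RLE factors, library size alone, no filter with blanks as 0, DESeq2 1.42.0, only the groups compared in the fit, all 48 libraries in the fit, the replicate number as a block, each library left out in turn, adjustment over the 16 class comparisons together, and the controls split between the disruptors. Added after the data were seen were blanks at the smallest listed count, leaving out the 2 libraries farthest from the others, and crossed replicate numbers. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups. The test code was tested on simulated data, 4 tables per comparison with 50 changed miRNAs each at 1.5, 2 or 4-fold, drawn from the real means, spreads and library sizes. Unchanged miRNAs were called at 0.198 to 1.12% by edgeR and at 0.889 to 1.74% by DESeq2.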

Results

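Small RNAs shorter than 100 bases were sequenced from early ovaries of CD1 mouse embryos at embryonic day 13.5, and mature miRNAs were counted. Pregnant females of the parental generation drank water with vehicle (DMSO, 0.3% v/v), MEHP at 35 mg per kg body weight per day or VZN at 50 mg per kg body weight per day. MEHP is the monoester metabolite of a widely used phthalate plasticiser, and VZN is vinclozolin, a fungicide with anti-androgenic activity. Embryos of the F1 generation were exposed directly in the uterus, and F2 and F3 descend from them. F2Sy is an F2 generation whose parents both came from the exposed lineage. Each pool of about 80 gonads was separated on a magnetic column into primordial germ cells (PGC), held back by anti-CD15 beads, and the remaining somatic cells of the early ovary (SC). By the labels' stain counts the germ cell fractions were 93 to 96% germ cells and the somatic fractions over 90% somatic. The 48 libraries form 24 groups of 2, one for each of 2 fractions, 3 exposures and 4 generation classes. The labels do not say whether the 2 libraries of a group came from separate litters or pools, so the p-values measure the spread between these libraries, which may be technical.

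The PGC libraries held 5966800 ± 1159500 listed miRNA counts (SD, n = 24; range 2932100 to 7946100) and the SC libraries 9928200 ± 1031500 (SD, n = 24; range 7460000 to 11762000). Listed totals were close between exposures within a fraction, at 6073000, 6155000 and 5672000 in PGC and 10050000, 10020000 and 9714000 in SC for control, MEHP and VZN (means, n = 8 each). A PGC library listed 386 ± 11.3 miRNAs and an SC library 444 ± 9.79 (SD, n = 24 each). The 2 libraries of a group correlated across miRNAs on the log2 scale with a median r of 0.967 in PGC (0.859 to 0.987) and 0.977 in SC (0.944 to 0.986); miRNAs are not independent replicates. The counts of every pair differed beyond read counting error, with a chi-square of at least 296.5 per degree of freedom, which covers counting error only and does not tell separate animals from separate library preparations. Library 2 of the VZN PGC F2Sy group, which held the fewest listed counts (2932100), and library 1 of the MEHP SC F3 group, which listed the fewest SC miRNAs (420), lay farthest from the other libraries of their fraction.

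The first comparison asked how the miRNAs of germ cells differ from those of the ovarian somatic cells, in the 8 control libraries of each fraction. Germ cells carried more of the miR-290-295 cluster, which is typical of early embryonic cells and primordial germ cells. They also carried more of a germline cluster on the X chromosome, of the miR-183 cluster (miR-183, miR-96 and miR-182) and of the miRNAs of the Sfmbt2 locus. The somatic fraction carried more of the Dlk1-Dio3 imprinted cluster, the let-7 family, whose maturation the pluripotency factor Lin28 blocks, and mesenchymal miRNAs such as miR-199a and miR-125b. Of 251 miRNAs tested, 105 were higher in PGC and 106 higher in SC (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median fold change over all 251 was 0.09 on the log2 scale, and 174 miRNAs differed by more than 1.

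The 10 miRNAs with the largest excess in PGC were miR-291b-5p, miR-291a-3p, miR-291b-3p, miR-20b-5p, miR-291a-5p, miR-363-3p, miR-471-3p, miR-292a-3p, miR-470-5p and miR-463-5p, with log2 fold changes from 4.88 to 5.14. The most abundant of them, miR-292a-3p, reached 87187 ± 6741 CPM (counts scaled by the library's listed total) in PGC and 3235 ± 1162 CPM in SC (SD, n = 8 each), a log2 fold change of 4.90 ± 0.21 (SE; edgeR adjusted p = 2.24e-18). The 10 with the largest excess in SC were miR-202-5p, miR-503-5p, miR-125b-5p, miR-199a-5p, miR-135a-5p, miR-134-5p, miR-351-5p, miR-1193-3p, miR-496a-3p and miR-199b-3p, with log2 fold changes from -3.61 to -4.29. miR-202-5p, a miRNA enriched in gonads, stood at 3226 ± 1692 CPM in PGC and 65435 ± 16775 CPM in SC (SD, n = 8 each), a log2 fold change of -4.29 ± 0.33 (SE; edgeR adjusted p = 4.57e-13). These 20 miRNAs had the same direction in all 4 generation classes. By the labels the PGC fractions were 93 to 96% germ cells and the SC fractions over 90% somatic. Cells of the other fraction shrink such fold changes, and no correction for purity was made. Their sizes and ranks may therefore be limited by the sort.

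Among the lists fixed before the data were examined, all 12 tested members of the miR-290-295 cluster were higher in PGC, with a list mean 4.88 log2 units higher. The examples miR-293-3p, miR-294-3p and miR-295-3p had log2 fold changes of 4.77, 4.62 and 4.66. All 9 tested members of the X-linked germline cluster were higher, with a list mean 5.02 higher; miR-465c-3p and miR-871-3p stood at 4.87 and 4.83. All 15 tested miRNAs of the Sfmbt2 locus were higher, with a list mean 2.47 higher, among them miR-467e-5p at 2.61 and miR-669b-5p at 2.68. Near-identical members of these families share reads, so values of single members are uncertain. All 3 tested members of the miR-302-367 cluster, another pluripotency cluster, were higher (miR-302b-3p 2.80, miR-302d-3p 2.63), as were all 3 of the miR-183 cluster (miR-183-5p 4.80, miR-182-5p 4.71, miR-96-5p 4.78). Of 15 members of the miR-17-92 cluster and its paralogs, which promote proliferation, 12 were higher (miR-92a-3p 1.93, miR-20a-5p 1.51), 1 was lower (miR-25-3p, -1.01) and 2 passed in neither direction.

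All 28 tested members of the Dlk1-Dio3 cluster were lower in PGC than in SC, with a list mean difference of -2.80; miR-127-3p, miR-379-5p and miR-411-5p had log2 fold changes of -2.57, -3.29 and -3.20. All 11 tested let-7 miRNAs were lower, with a list mean difference of -2.42, from let-7f-5p at -1.30 to let-7e-5p at -3.22. Of 9 mesenchymal miRNAs 8 were lower (miR-10b-5p -3.19, miR-99a-5p -3.52, miR-199b-3p -3.61) and 1, miR-140-5p, was higher at 0.58. The erythroid miR-451a (-2.59) and the endothelial miR-126a-3p (-1.96) were lower in PGC, the neuronal miR-9-5p was higher (4.79), and the leukocyte miR-150-5p stood at 0.42 (edgeR adjusted p = 0.164). The miR-15/16 family, which targets the anti-apoptotic gene Bcl2, went both ways, with miR-16-5p at 1.37 and miR-322-5p at -3.50; 3 of its 7 tested members were higher, 1 lower and 3 passed in neither direction. Of 6 p53-responsive miRNAs 1 was higher (miR-34a-5p, 1.32), 4 were lower (among them miR-192-5p, -0.66) and 1 passed in neither direction. The lower miR-34b-3p (-0.39) lost its call in 10 of 23 alternatives, at -0.16 without library 1 of control SC F2Sy, and miR-34c-3p, which did not pass, passed as lower in 5. Of 3 miR-29 miRNAs, which target the de novo DNA methyltransferases, 2 were higher (miR-29a-3p, 3.77). Of the miR-200 family only miR-200c-3p (4.42) passed among 4 tested, and of miR-21a-5p and miR-23b-3p the latter was lower (-1.20) and the former stood at 0.17. Of 23 alternatives, miR-15a-5p lost its call as higher in 4, and miR-429-3p, miR-200b-3p and miR-29c-3p, which did not pass, passed as higher in 5, 2 and 3. The muscle, liver and hypoxia lists had no member listed in all 48 libraries.

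camera, with a preset correlation of 0.01 between miRNAs, called 7 of the 10 lists with at least 4 members: miR-290-295, X-linked, Sfmbt2 and miR-17-92 as higher in PGC, and Dlk1-Dio3, let-7 and mesenchymal as lower. With an estimated correlation it called none, at adjusted p = 0.176, 0.252, 0.197, 0.216, 0.0765, 0.216 and 0.197 for these 7 lists. The miR-200, p53 and miR-15/16 lists were not called, at camera adjusted p = 0.343, 0.619 and 0.550. An exact permutation of list means between fractions within generation classes gave a two-sided p of 0.00154, the smallest it can give, for 15 of the 18 lists with a tested member (adjusted p = 0.00185). The exact permutation p was 0.00772 for the p53 list, 0.179 for the leukocyte miRNA and 0.809 for the miR-15/16 list. Adjusted over the list alone, the counts were those over all miRNAs for each of these lists. miR-200a-3p (0.09) and miR-15b-5p (0.06), which did not pass, changed sign when only library size was used for scaling, at -0.02 and -0.05; that scaling moved the median of all 251 fold changes by -0.11.

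**Figure D1:**
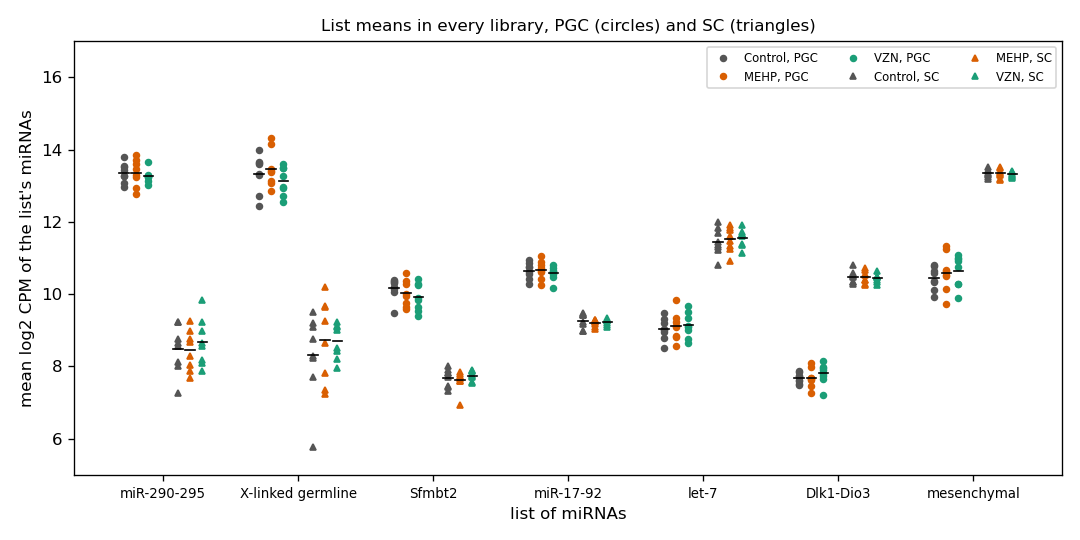
Mean log2 CPM of the tested miRNAs of 7 lists (x axis) in each of the 48 libraries (y axis, log2 CPM), with circles for PGC, triangles for SC, colours for the exposure and black bars for the mean of 8 libraries. The fractions lie apart in every one of these lists, by 4.88 log2 units for miR-290-295 and -2.80 for Dlk1-Dio3 in the controls, and the exposures overlap within each fraction.

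The fit covers miRNAs listed in all 48 libraries and so leaves out those that are abundant in one fraction and left blank in the other. Such miRNAs, picked out after their values were seen, were taken as listed in all 8 control libraries of one fraction and blank in all 8 of the other. There were 9 in PGC, with means from 73.2 to 227 CPM, beside a highest smallest listed value of 14.6 CPM in the control SC libraries. They include miR-471-5p (227 ± 112 CPM) and miR-742-5p (132 ± 40.8 CPM) of the X-linked cluster, miR-153-3p (219 ± 54.8 CPM) and miR-211-5p (107 ± 22.9 CPM; SD, n = 8 each). There were 69 in SC, from 21.6 to 274 CPM, of which 61 lay above the highest smallest listed value of the control PGC libraries (30.5 CPM). Of the 69, 27 belong to the Dlk1-Dio3 list, 8 to the mesenchymal list and 2 to the erythroid list. The X-linked cluster also had a member among them, miR-547-3p (91.7 ± 21.4 CPM, SD, n = 8), listed in all 24 SC libraries and in none of the 24 PGC libraries. It had 3 members among the 9 of PGC, of which miR-463-3p was listed in 1 of the 24 SC libraries. miR-1251-5p (274 ± 89.1 CPM), miR-130b-3p (271 ± 110 CPM) and miR-666-3p (205 ± 52.1 CPM; SD, n = 8 each) were listed in all 24 SC libraries and in none of the 24 PGC libraries.

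The next comparisons asked whether exposure of the founding female left a difference in the germ cell miRNAs of its descendants, averaged over the 4 generation classes. In PGC of the MEHP lineage none of the 303 tested miRNAs differed from control by edgeR (smallest adjusted p = 0.995; 5 at an unadjusted p under 0.05; DESeq2 0 calls). The smallest p-values belonged to miR-200a-3p, at 1783 ± 658 CPM against 1244 ± 280 CPM in control, and miR-10a-5p, at 3074 ± 1997 CPM against 1762 ± 439 CPM (SD, n = 8 each). Their log2 fold changes were 0.49 ± 0.18 and 0.72 ± 0.28 (SE), and 0.32 and 0.25 without library 1 of the MEHP F1 group. The abundant germ cell miRNAs lay close to control, with miR-292a-3p at -0.07 ± 0.13 and miR-183-5p at -0.02 ± 0.17 (log2 fold change, SE). None of the members of any list passed, over all miRNAs or adjusted over the list alone. camera with its preset correlation called 4 of 13 lists, miR-200 (median log2 fold change 0.45) and X-linked (0.12) as higher and Sfmbt2 (-0.13) and miR-302-367 (-0.16) as lower. With an estimated correlation the adjusted p of these lists was 0.115, 0.488, 0.488 and 0.488, and no list passed the exact permutation of list means (smallest p = 0.088, for the miR-200 family). The let-7 list stood at 0.07 and the mesenchymal list, a marker of somatic cells, at 0.16 (list mean, MEHP minus control). Without library 2 of the MEHP F1 group 1 miRNA was called, miR-10a-5p at 0.92 (edgeR adjusted p = 0.0383).

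In PGC of the VZN lineage none of the 303 miRNAs differed from control on average (edgeR, smallest adjusted p = 0.935; 8 at an unadjusted p under 0.05; DESeq2 0 calls). miR-652-3p had the smallest p, at 24091 ± 5723 CPM against 28141 ± 2598 CPM in control (SD, n = 8 each), a log2 fold change of -0.29 ± 0.09 (SE). miR-463-3p of the X-linked cluster followed, at 54.2 ± 16.2 CPM against 77.6 ± 26.3 CPM, a log2 fold change of -0.53 ± 0.20 (SE). Among the most abundant miRNAs, miR-292a-3p stood at -0.09 ± 0.13 and miR-92a-3p at -0.02 ± 0.10 (log2 fold change, SE). camera with its preset correlation called the Dlk1-Dio3 list as higher (median 0.20; miR-379-5p 0.41, miR-411-5p 0.35) and the Sfmbt2 (-0.13; miR-467a-5p -0.41) and X-linked (-0.21; miR-871-3p -0.36) lists as lower. With an estimated correlation the adjusted p was 0.795 for each, and none passed the exact permutation of list means (smallest p = 0.193, for Dlk1-Dio3). The mesenchymal list stood at 0.19 in the same libraries (list mean, VZN minus control; exact permutation p = 0.242). Without library 2 of the VZN F2Sy group 7 miRNAs were called, and without library 1 of it 2 were.

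In the somatic fraction none of the 355 tested miRNAs differed from control on average in the MEHP lineage (edgeR, smallest adjusted p = 0.999; 10 at an unadjusted p under 0.05) or in the VZN lineage (0.994; 5); DESeq2 called 0 in both. miR-107-3p, a p53-responsive miRNA, had the smallest p in each, at 157 ± 28.3 CPM with MEHP and 184 ± 44.2 CPM with VZN against 422 ± 485 CPM in control (SD, n = 8 each), with log2 fold changes of -1.09 and -0.88. The control mean rests on library 2 of F1 (833 CPM) and library 1 of F3 (1478 CPM); the other 6 control libraries held 145 to 212 CPM. Without the former the log2 fold changes were -0.68 and -0.47, and without the latter -0.59 and -0.37. let-7d-3p followed for MEHP, at 0.49 ± 0.16 (log2 fold change, SE), and miR-1843a-3p for VZN, at 0.33 ± 0.14. The erythroid miR-451a and miR-486b-5p stood at 0.70 ± 0.26 and 0.57 ± 0.25 with MEHP; neither passed over all miRNAs, and both passed adjusted over the list alone, which depended on single libraries. They stood at 0.30 and 0.33 without library 2 of MEHP F2Sy, which held 85923 CPM of miR-451a (list-alone edgeR adjusted p = 0.174 for each). The mean of the 2 differed from control by 1.09, 0.70 and 1.33 in F1, F2 and F2Sy and by -0.73 in F3 (log2, MEHP minus control), where miR-451a held 13995 and 15496 CPM against 30310 and 19290 CPM in control. miR-107-3p for MEHP and the hypoxia miRNA miR-210-3p for VZN (-0.45 ± 0.19) also passed over their list alone, and no longer did without library 2 of control F1 (-0.68 and -0.27), among other libraries.

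In the same fraction camera with its preset correlation called the X-linked (median log2 fold change 0.16) and miR-200 (0.23) lists as higher with MEHP, and the miR-290-295 (0.20) and X-linked (0.16) lists as higher with VZN. With an estimated correlation the adjusted p was 0.581 and 0.231 for MEHP and 0.570 for each list of VZN. The miR-200 list mean was 0.20 higher with MEHP (exact permutation p = 0.0494) and 0.17 higher with VZN (exact permutation p = 0.0386), the smallest of 19 lists in each, and neither passed after adjustment (0.570 and 0.631). Mesenchymal markers stood at -0.02 and 0.01 (list mean, exposed minus control). In both fractions the median, the mean and camera's direction differed in sign only for lists that camera did not call, such as Dlk1-Dio3 with MEHP in PGC (median 0.02, camera lower). Without library 2 of the MEHP F3 group, which leaves the atypical library 1, 5 miRNAs were called for MEHP.

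**Figure D2:**
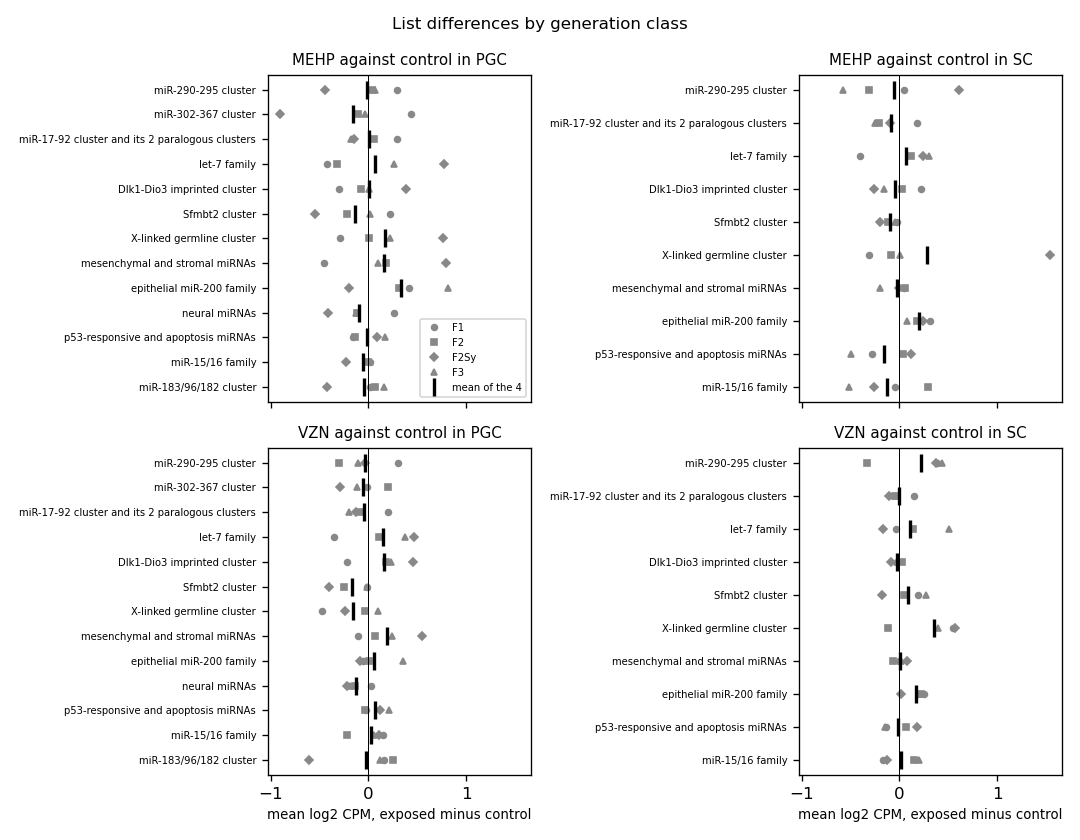
Difference between exposed and control libraries in the mean log2 CPM (x axis) of each list with at least 4 members (y axis), for MEHP and VZN in PGC and SC, with a grey symbol per generation class (2 libraries against 2) and a black bar for the mean of the 4 classes. The black bars lie close to 0, and the widest single difference is the X-linked list of MEHP SC F2Sy at 1.54.

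These averages leave limited room for broad changes of the same direction and similar size in all generation classes, among the miRNAs tested. A change in a single class is diluted in the mean, and changes of opposite direction cancel. The intervals and recovery rates given here concern the mean, so they do not limit changes confined to single classes. The 95% interval of a fold change had a median extent of plus or minus 0.41 log2 units in PGC and 0.35 in SC. It lay within plus or minus 1 log2 unit for 288 and 279 of 303 miRNAs in PGC (MEHP and VZN) and for 334 and 340 of 355 in SC. In simulated tables built from the MEHP libraries the same test recovered 92.6% of 2-fold changes in PGC (303 miRNAs) and 92.6% in SC (355 miRNAs), and 44.1% and 61.8% of 1.5-fold changes. Each table held 50 changed miRNAs. With fewer changed miRNAs the adjustment is stricter, and recovery may be lower. Whether a miRNA was listed was also compared with exposure. By Fisher's exact test on the number of listing libraries (8 against 8) the smallest p was 0.0256 for miR-92b-5p, listed in 5 MEHP and 0 control SC libraries, and 0.0406 for miR-122-5p, listed in 6 VZN and 1 control SC libraries, and neither passed after adjustment.

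Within single generation classes, where 2 exposed libraries were compared with 2 controls, 1 call was made in 16 comparisons. In F2Sy germ cells of the VZN lineage miR-652-3p fell by 1.08 on the log2 scale (95% interval plus or minus 0.39; edgeR adjusted p = 0.00569). The exposed libraries held 15674 and 14985 CPM and the other 22 PGC libraries 23829 to 32199 CPM. In SC miR-652-3p stood at 24136 and 17992 CPM in VZN F2Sy, against 21165 and 17583 CPM in control F2Sy. The 2 libraries of VZN SC F3 lay far apart, at 6979 and 19458 CPM. The fold change in VZN PGC F2Sy was -1.15 by DESeq2 (adjusted p = 1.76e-06). The call ended without control library 1 (log2 fold change -1.20, edgeR adjusted p = 0.0619), without control library 2 (-1.17, 0.0751), with only these 4 libraries in the fit (-1.13, 0.996) and with adjustment over the 16 comparisons together (0.0989), with a range of adjusted p over its alternatives from 1.76e-06 to 0.996. Whether the VZN effect on it differed between the 4 classes did not pass by edgeR (adjusted p = 0.313) and passed by DESeq2 (0.00579). Its difference between F2Sy and F2 was -1.14 and did not pass by edgeR (adjusted p = 0.117), but passed by DESeq2 (0.00637) and by edgeR without library 1 (0.0141) or library 2 (0.0410) of VZN F2Sy.

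**Figure D3:**
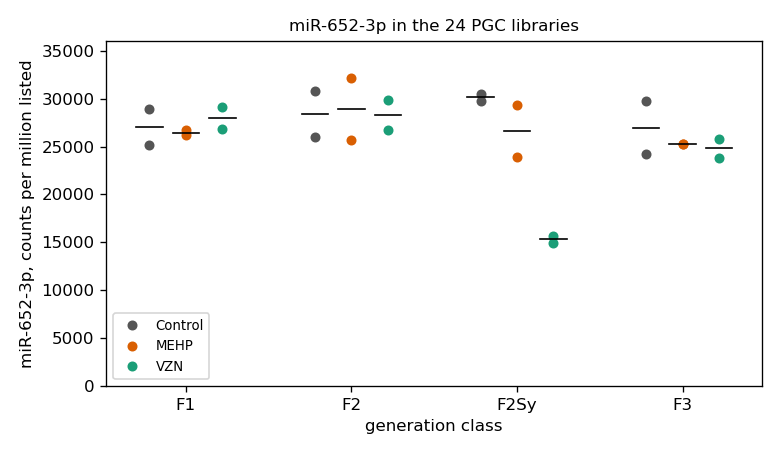
miR-652-3p in CPM (y axis, from 0) in the 24 PGC libraries by generation class (x axis), with a point per library, colours for the exposure and a black bar for each group's mean. The 2 VZN F2Sy libraries stand at 14985 and 15674 CPM, below the 23829 to 32199 CPM of the other 22.

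In the other 15 class comparisons edgeR called no miRNA. The numbers at an unadjusted p under 0.05 in F1, F2, F2Sy and F3 were 1, 0, 27 and 9 for MEHP in PGC, 14, 15, 24 and 42 for MEHP in SC, and 11, 1, 7 and 14 for VZN in SC. For VZN in PGC they were 8, 5, 22 and 1, the 22 including miR-652-3p. DESeq2 called 2, 1 and 6 miRNAs for MEHP in SC at F2, F2Sy and F3, 1 each for VZN in SC at F1 and F2Sy, 1 for VZN in PGC at F2Sy and 0 in the other 10. In tables simulated on the MEHP F2Sy comparisons DESeq2 called more unchanged miRNAs than edgeR. The rates were 0.889% against 0.198% in PGC and 1.39% against 0.328% in SC. The 2 miRNAs with the smallest p of each of these 15 comparisons follow, as log2 fold changes with their SE, with the value without a library where that moved it by more than 1.5 times or changed the call.

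For MEHP in PGC, miR-203-3p and miR-293-5p stood at 0.74 ± 0.29 and 0.63 ± 0.30 in F1 (0.40 without MEHP library 1 and 0.23 without MEHP library 2; edgeR adjusted p = 0.996 for each). In F2 miR-196b-5p and miR-346-5p stood at 0.82 ± 0.40 and 0.51 ± 0.28 (0.52 and 0.32 without MEHP library 2, and 0.34 for the latter without control library 2; edgeR adjusted p = 0.995). In F2Sy miR-199b-3p and miR-28a-5p stood at 1.48 ± 0.44 and 1.24 ± 0.39 (edgeR adjusted p = 0.506). miR-199b-3p is among the miRNAs higher in SC. In the same libraries the mesenchymal, let-7 and Dlk1-Dio3 lists stood 0.80, 0.77 and 0.38 higher than control and the miR-302-367 list stood at -0.91 (list means, MEHP minus control). The X-linked list, which a somatic share would lower, stood 0.761 higher than control. In F3 miR-204-5p stood at 2.19 ± 0.67 and miR-429-3p, of the miR-200 family, at 1.14 ± 0.35 (0.76 without MEHP library 2; edgeR adjusted p = 0.615).

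For MEHP in SC, miR-410-5p and miR-412-5p stood at 0.71 ± 0.24 and 0.64 ± 0.22 in F1 (0.45 without MEHP library 2 and 0.42 without control library 2; edgeR adjusted p = 0.937). In F2 the 2 lowest values of miR-183-5p among the 24 SC libraries, 335 and 292 CPM, were those of MEHP, against 1439 and 1972 CPM in its controls, a log2 fold change of -2.42 ± 0.51 (edgeR adjusted p = 0.0853). It passed in 3 of 12 alternatives, which were DESeq2 (adjusted p = 5.88e-05), all 48 libraries in the fit (0.00157) and library size only (0.0485), with fold changes from -2.23 to -2.60 and adjusted p up to 0.530. Across SC libraries the cluster of miR-183-5p, higher in PGC, rose with the miR-290-295 list (r = 0.732, 0.782 within groups, 0.563 without 2 libraries). The values of miR-183-5p in SC may therefore depend in part on carried-over germ cells, which was not tested directly. A loss of germ cells behind this whole fall would also lower the miR-290-295 and X-linked lists (12 and 11 members tested in SC). In MEHP SC F2 12 of 355 miRNAs moved by more than 1 log2 unit either way, and camera called 0 of 10 lists. These values argue against such a loss as the whole cause. miR-22-3p followed at -0.66 ± 0.19 (edgeR adjusted p = 0.518) and passed by DESeq2 (0.0166). In F2Sy miR-451a stood at 2.15 ± 0.53 (edgeR adjusted p = 0.345; DESeq2 0.00139), with 85923 CPM in library 2 and 18173 CPM in library 1; it stood at 0.58 without the former and at 2.89, called, without the latter. miR-196b-5p stood at -0.71 ± 0.24 (edgeR adjusted p = 0.629), and at -0.41 without control library 2. In F3 miR-760-3p and miR-222-3p stood at 1.68 ± 0.37 and 1.33 ± 0.33 (edgeR adjusted p = 0.129 and 0.195) and passed by DESeq2 (0.00149 and 0.00722) and with all 48 libraries in the fit (0.0119 each). miR-760-3p stood at 0.88 without the atypical library 1 and at 2.19, called, without library 2; miR-222-3p stood at 0.86 without control library 2 and was called without control library 1 (2.03) or MEHP library 2 (1.65).

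For VZN in PGC, miR-471-3p and miR-7a-1-3p stood at -1.05 ± 0.40 and 1.28 ± 0.50 in F1 (-0.32 without control library 1 and 0.40 without VZN library 1; edgeR adjusted p = 0.988). In F2 miR-324-5p and miR-29a-3p stood at -1.53 ± 0.55 and -0.73 ± 0.27 (edgeR adjusted p = 0.996). In F3 miR-1839-5p stood at 0.88 ± 0.35, at 1.65 without control library 1 and at 0.48 without control library 2, and miR-291a-3p at -0.63 ± 0.30, or -0.39 without VZN library 2 (edgeR adjusted p = 0.981).

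For VZN in SC, miR-3102-3p and miR-130b-3p stood at -2.96 ± 0.83 and -1.10 ± 0.33 in F1 (edgeR adjusted p = 0.808). Both were called without control library 1 (-3.73 and -1.50) and stood at -1.25 and -0.53 without control library 2; DESeq2 called the former (adjusted p = 0.0133). In F2 miR-342-3p and miR-1843a-3p stood at 0.64 ± 0.27 and 0.59 ± 0.28 (0.23 for the latter without VZN library 2; edgeR adjusted p = 1). In F2Sy miR-3968 stood at 4.59 ± 1.29, at 384 ± 246 CPM against 15.2 ± 3.61 CPM in control (SD, n = 2 each), and miR-1843a-3p at 0.92 ± 0.28 (edgeR adjusted p = 0.879). DESeq2 called miR-3968 (adjusted p = 0.00684), which also differed widely between the control classes. In F3 miR-125b-5p and miR-760-3p stood at 1.71 ± 0.54 and 1.01 ± 0.37 (edgeR adjusted p = 0.906), the former at 0.25 without VZN library 2 and at 2.42, called, without VZN library 1.

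The median 95% interval in these comparisons was about plus or minus 0.83 log2 units in PGC and 0.69 in SC, and in tables simulated on the MEHP F2Sy comparisons 16.2% of 2-fold and 87.5% of 4-fold changes were recovered in PGC (303 miRNAs), and 29.4% and 84.4% in SC (355 miRNAs). These tables also held 50 changed miRNAs each, and recovery may be lower with fewer. camera with its preset correlation called 0 to 9 of the 10 or 13 lists in a class comparison, most in MEHP PGC F1 (9) and F2Sy (8), and with an estimated correlation it called none in any (smallest adjusted p = 0.0525, for the miR-200 family in MEHP PGC F3, median 0.81). No member of any list passed in these comparisons over all miRNAs. Without library 2 of MEHP SC F3, leaving the atypical library 1, 81 miRNAs were called in that comparison, and without either control library of it 1 was. Without library 1 of VZN PGC F2Sy 19 miRNAs were called and without library 2 there were 16. Without library 1 of control SC F1, 4 were called for VZN and 1 for MEHP in SC F1; without library 1 of MEHP SC F2Sy 1 was called there, and without library 1 of VZN SC F3 1 was called there.

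Whether the exposure effect differed between the generation classes was tested jointly over the 4 classes, and edgeR called no miRNA. The numbers at an unadjusted p under 0.05 were 8 and 33 for MEHP in PGC and SC and 6 and 9 for VZN; DESeq2 called 0, 14, 1 and 1. The smallest edgeR p-values belonged to miR-199b-3p for MEHP in PGC, miR-183-5p for MEHP in SC, miR-652-3p for VZN in PGC and miR-3968 for VZN in SC (adjusted p = 0.986, 0.444, 0.313 and 0.837). Their effects in F2, F2Sy or F3 differed from that in F1 by up to 2.36, -2.37, -1.13 and 8.30 log2 units, and DESeq2 called the last 3 (adjusted p = 0.0154, 0.00579 and 0.00858). Next came miR-192-5p (1.37), miR-409-3p (-0.91), miR-183-5p (-1.27) and miR-375-3p (-2.94) in the same order. miR-409-3p passed by DESeq2 (adjusted p = 0.0417) and, at -0.91, without library 2 of MEHP SC F3. miR-183-5p stood at -2.21, called, without library 1 of VZN PGC F2Sy and at -0.79 without library 2, and miR-375-3p passed with only the groups compared in the fit (edgeR adjusted p = 0.0333). Without library 2 of MEHP SC F3 45 miRNAs were called and without library 1 of MEHP SC F2Sy 1 was; without libraries 1 and 2 of VZN PGC F2Sy in turn, 6 and 7 were called. When both parents came from the exposed lineage (F2Sy), the effect was compared with that in F2, where edgeR again called none. The numbers at an unadjusted p under 0.05 were 7 and 22 for MEHP in PGC and SC and 9 and 3 for VZN, and DESeq2 called 0, 5, 1 and 0. miR-183-5p in MEHP SC had the smallest p of its comparison, with a difference of 2.89 ± 0.70 (log2 units, SE; edgeR adjusted p = 0.297). It passed in 3 of 16 alternatives, which were DESeq2 (adjusted p = 0.00268), all 48 libraries in the fit (0.0169) and only the groups compared (0.0193), with differences from 2.64 to 3.19 and adjusted p up to 0.994. miR-196b-5p followed at -1.19 ± 0.34 (edgeR adjusted p = 0.319; DESeq2 0.0259). let-7d-5p and miR-222-3p in MEHP PGC stood at 1.91 ± 0.72 and -1.19 ± 0.45 (edgeR adjusted p = 0.856), the latter at -0.75 and -1.82 without libraries 1 and 2 of control PGC F2. In VZN PGC miR-324-5p stood at 2.58 ± 0.77 (edgeR adjusted p = 0.583), and in VZN SC miR-3968 at 4.84 ± 1.65 and miR-342-3p at -0.90 ± 0.38, or -0.57 without library 1 of VZN SC F2Sy (edgeR adjusted p = 0.996). Without libraries 1 and 2 of VZN PGC F2Sy in turn, 15 and 11 were called, and without library 1 of MEHP SC F2 1 was.

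The mean effect was compared between germ cells and somatic cells in the 251 miRNAs tested in both. edgeR and DESeq2 called 0 for each disruptor, with 2 (MEHP) and 3 (VZN) at an unadjusted p under 0.05. The smallest p-values belonged to miR-760-3p (-0.58 ± 0.26, PGC minus SC, log2, SE; -0.38 without library 1 of MEHP SC F3) for MEHP and miR-134-5p of the Dlk1-Dio3 cluster (0.61 ± 0.28) for VZN. miR-10a-5p followed for MEHP at 0.68 ± 0.31, or 0.22 without library 1 of MEHP PGC F1, and miR-28a-5p for VZN at 0.43 ± 0.20, or 0.26 without library 1 of VZN PGC F2Sy. The median 95% interval of this difference was plus or minus 0.53. Without library 2 of VZN PGC F2Sy 4 miRNAs were called for VZN.

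MEHP and VZN, given at different doses, were compared directly. No miRNA differed between them in PGC (edgeR, smallest adjusted p = 0.874; 13 at an unadjusted p under 0.05) or SC (0.968; 5), and DESeq2 called 0 in both. miR-463-3p in PGC stood at 0.67 ± 0.20 and miR-183-5p in SC at -0.75 ± 0.24 (log2, MEHP minus VZN, SE), the latter at -0.42 without library 2 of VZN F3. miR-409-3p in PGC followed at -0.33 ± 0.13 and miR-335-5p in SC at -0.33 ± 0.14, the latter called at -0.45 without library 2 of MEHP SC F3. The 95% interval lay within plus or minus 1 log2 unit for 282 of 303 miRNAs in PGC and 340 of 355 in SC. Without libraries 1 and 2 of VZN PGC F2Sy in turn, 3 and 5 miRNAs were called in PGC, and without library 2 of MEHP SC F3 15 were called in SC. The mean fold changes of MEHP and VZN correlated across miRNAs with r = 0.295 in PGC and 0.583 in SC. Unchanged groups simulated against the same controls gave a mean r of 0.496 (0.336 to 0.627) and 0.497 (0.400 to 0.593). The covariance was 0.0106 in PGC, below the simulated 0.0212 to 0.0475 (mean 0.0319), and 0.0205 in SC, within the simulated 0.0176 to 0.0325 (mean 0.0247). In PGC r also lay below its simulated range, for which no cause was tested. With the controls split between the disruptors, r was 0.01 and -0.42 in PGC and -0.15 and -0.24 in SC.

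The control groups, none of which was exposed, gave the background between generation classes. No miRNA differed among the 4 control classes in PGC (edgeR, smallest adjusted p = 0.991; 2 at an unadjusted p under 0.05; DESeq2 0 calls) or SC (0.514; 14; DESeq2 5 calls). The smallest p-values belonged to miR-195a-5p and miR-199a-5p in PGC and to the erythroid miR-486b-5p and miR-3968 in SC. Their F2, F2Sy or F3 controls differed from those of F1 by up to 1.88, -1.29, 1.75 and -6.24 log2 units, and DESeq2 called the last 2 (adjusted p = 0.0098 each). Without library 1 of control SC F1 1 miRNA was called.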

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

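The tests of somatic or germ cells in the other fraction, of scaling, of single libraries, of chance across the class comparisons and the splits of the libraries were chosen after the results were seen; the 2 tests of listed totals were not.

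Among the 8 libraries of an exposure and fraction, 6 values lay farther from the others than Dixon's 95% limit allows. Chance gives about 1 in 20, or 3.9 of the 78 sets tested. Library 2 of control SC F1 had a mean of 8.85 log2 CPM for the miR-183 cluster, and the other 7 control SC libraries had 9.57 to 10.2. Library 2 of VZN SC F3 had 11.18 for the same cluster, and the other VZN SC libraries had 9.49 to 10.2. Library 1 of MEHP SC F3 listed 420 miRNAs, beside 437 to 452, and had means of 5.01 for miR-302-367 (others 6.21 to 7.07) and 6.93 for the Sfmbt2 list (others 7.58 to 7.82). Library 2 of MEHP SC F2Sy had 16.39 log2 CPM of the erythroid miR-451a, beside 13.8 to 14.3.

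Splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included, set the real number of calls beside that of other groupings. For PGC against SC 1 of the 100 splits gave as many calls, the real one with 211. The highest other gave 196 and the median of the others was 0. A rank of 1 in 100 is the best this number of splits can give. For the comparisons without calls the splits say nothing about chance, since with 0 real calls all 100 of 100 give as many by construction. Their highest other counts were 1, 14, 3 and 1 for the means of MEHP in PGC and SC and VZN in PGC and SC. They were 9 and 1 for the difference of the MEHP and VZN effects between fractions, and 7 and 1 for MEHP against VZN in PGC and SC.

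In VZN PGC F2Sy, miR-652-3p fell by 1.08 on the log2 scale. It was 0.57 higher in PGC than in SC (95% interval plus or minus 0.28), so at these estimates even a full replacement by somatic cells would not give the fall. With both intervals at their most favourable ends a somatic share of 86.2% is needed, which would change the miR-290-295 list by -2.57. That list stood at 12.09 against 12.12 log2 CPM, a difference of -0.0345 (SD within groups 0.319), which argues against such a share. A smaller share is not excluded. miR-202-5p, higher in SC, stood at 3765 and 3536 CPM against 1164 and 2556 CPM in control F2Sy. miR-183-5p, higher in PGC, stood at 32571 and 13283 CPM against 47717 and 49900 CPM. Both go the way a somatic share would move them from control F2Sy. Over all 8 control PGC libraries miR-202-5p ranged from 1164 to 5312 CPM and miR-183-5p from 27662 to 49900 CPM. Of the values in VZN PGC F2Sy, only the 13283 CPM of miR-183-5p in library 2 lay outside these ranges. The scaling with the weakest effect left -0.9721 (edgeR adjusted p = 0.0214; range over the alternatives 1.76e-06 to 0.996), and the weaker log2 fold change with either exposed library left out was -1.024, which argues against scaling and against 1 unusual library as the whole cause. Chance among all class comparisons stays open, since adjustment over the 16 together gives 0.0989. An effect of the VZN lineage also stays open and was not tested apart from it.

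Across the 24 PGC libraries the Dlk1-Dio3 and mesenchymal lists rose together (r = 0.892, permutation p = 1e-05, the smallest the permutations can give; rho = 0.919, p = 1e-05; adjusted p = 9e-04 over 90 relations; r = 0.907 without the 2 libraries farthest from the median). Within groups r was 0.908. A varying share of somatic cells, which the CD15 sort should remove, is a candidate explanation: it requires the let-7 list, also higher in SC, to rise with the mesenchymal list, and r was 0.636 (permutation p = 0.00085; rho = 0.597, p = 0.00253; adjusted p = 0.00579; r = 0.524 without 2). Within exposures this r was 0.296 in control, 0.933 in MEHP and 0.450 in VZN libraries. Of the lists higher in PGC, Sfmbt2 (r = -0.748), miR-302-367 (-0.678) and miR-183 (-0.577) fell as the mesenchymal list rose (permutation adjusted p = 0.00124, 0.004 and 0.0113), while r was -0.410 for miR-290-295, -0.302 for miR-17-92, -0.0127 for X-linked and 0.102 for miR-200 (0.107, 0.275, 0.999 and 0.754). In the miR-200 list only miR-200c-3p passed as higher in PGC. The mesenchymal list did not follow the listed total, with r = 0.0204 (permutation p = 0.926, rho = 0.0974, p = 0.651), which argues against the listed total as a cause. Sequencing depth itself is not known and was not tested. No biological explanation was tested.

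Across the 24 SC libraries the X-linked and miR-290-295 lists rose together (r = 0.782, permutation p = 5e-05; rho = 0.767, p = 3e-05; adjusted p = 0.00113 over the same 90 relations; r = 0.774 without 2; r = 0.740 within groups). A varying share of germ cells, which the column should hold back, stays open: the miR-183 cluster, also higher in PGC, rose with the X-linked list (r = 0.516, permutation p = 0.0109; rho = 0.651, p = 0.00079; adjusted p = 0.0338), at r = 0.397 without 2. For other lists higher in PGC, r with the X-linked list was -0.167 for miR-302-367, 0.137 for Sfmbt2 and 0.233 for miR-17-92 (permutation adjusted p = 0.568, 0.659 and 0.429). Their excess in PGC is smaller, so a given share of germ cells would move them less. For miR-200 r was 0.580 (permutation adjusted p = 0.0113), or 0.813 within groups. Of its 4 tested members only miR-200c-3p passed as higher in PGC, so germ cells would move its other members little and this r is no support for them. Of the lists higher in SC, which such a share would lower, Dlk1-Dio3 had r = -0.587, mesenchymal -0.429 and let-7 0.444, or 0.722 within groups (permutation adjusted p = 0.011, 0.0895 and 0.0774). The rise of let-7 goes against this explanation and the other 2 go with it, so these values do not decide. The X-linked list did not follow the listed total, with r = -0.106 (permutation p = 0.624, rho = -0.170, p = 0.428), which argues against the listed total as a cause. Sequencing depth itself was not tested here either. No biological explanation was tested.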

How the results depend on the processing

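Blanks at the smallest listed count, leaving out both libraries farthest from the others, and crossed replicate numbers were chosen after the data were seen. Of 1060 values of named miRNAs under other settings than a left-out library, 1020 kept their direction and side of the threshold, 5 no longer passed, 29 newly passed and 6 reversed; with a library left out, 1800 of 1836 kept both, 12 no longer passed, 23 newly passed and 1 reversed. Of 381 counts of calls and other main values, 308 were kept, counts within 1.5 times, under other settings, 70 moved and 3 reversed, and of 432 with a library left out 377 were kept. The cause was not tested for any of the changes unless the setting itself shows it.

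For PGC against SC, 211 calls of 251 became 407 of 563 with blanks as 0 and 489 of 563 with blanks at the smallest listed count. More miRNAs are tested there, but the smallest listed count averaged 24.1 CPM in PGC and 13.6 CPM in SC. Filled blanks thus differ between the fractions by the fill itself, so 489 is not a count of real differences. The other settings gave 205 to 216. miR-200a-3p and miR-15b-5p, neither called, reversed with library size only (-0.01874 and -0.04728), blanks as 0 (-0.05629 and -0.09714) and blanks at the smallest listed count (-0.05522 and -0.08863), and miR-200a-3p also without library 1 of control PGC F2Sy (-0.04865; left-out range -0.05 to 0.24).

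DESeq2 called 2, 1 and 6 miRNAs for MEHP in SC at F2, F2Sy and F3, 1 each for VZN in SC at F1 and F2Sy, 14, 1 and 1 for the difference between classes of MEHP in SC, VZN in PGC and VZN in SC, 5 and 1 for F2Sy against F2 of MEHP in SC and VZN in PGC, and 5 for the SC controls. With only the groups compared in the fit, VZN PGC F2Sy had 0 calls, the VZN difference between classes in SC 1 and F2Sy against F2 of MEHP in SC 1. With all 48 libraries in the fit MEHP SC F2 had 1, MEHP SC F3 3, VZN PGC F2Sy 2 and F2Sy against F2 of MEHP in SC 1. Library size only gave 1 for MEHP SC F2. Blanks at the smallest listed count gave 2 for MEHP SC F2Sy and 1 for F2Sy against F2 of MEHP in SC. Without both libraries farthest from the others, VZN had 7 calls in the PGC mean, 16 in PGC F2Sy, 7 in the difference between classes in PGC, 11 in F2Sy against F2 in PGC and 5 in the difference between fractions, and MEHP against VZN in PGC had 5. Adjusted over the 16 class comparisons together, 0 remained of 1.

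Leaving out 1 library at a time gave ranges of 0 to 1 (MEHP), 0 to 7 (VZN) for the PGC means and 0 to 5 for the MEHP SC mean; 0 to 1 for MEHP SC F1, 0 to 1 for F2Sy and 0 to 81 for F3; 0 to 19 for VZN PGC F2Sy; 0 to 4 for VZN SC F1 and 0 to 1 for F3. The ranges were 0 to 45 for the MEHP difference between classes in SC, 0 to 7 for that of VZN in PGC, 0 to 1 for F2Sy against F2 of MEHP in SC, 0 to 15 for that of VZN in PGC, 0 to 4 for the VZN difference between fractions, 0 to 5 and 0 to 15 for MEHP against VZN in PGC and SC, and 0 to 1 for the SC controls. The values of 81 and 45, and 15 in SC, came without library 2 of MEHP SC F3, those of 19 and of 15 in PGC without library 1 of VZN PGC F2Sy, and that of 7 for VZN without its library 2. Lists called by camera ranged from 1 to 7 for the MEHP PGC mean, 0 to 3 for MEHP SC, 0 to 6 for VZN PGC and 0 to 6 for VZN SC.

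With an estimated correlation camera called 0 lists in every comparison, PGC against SC included. fry called all 10 tested lists for PGC against SC (smallest fry adjusted p = 1.37e-20) and 0 in every exposure comparison. Library size only gave 4 lists for the VZN SC mean. With the controls split between the disruptors, the correlation of MEHP and VZN effects was 0.00663 and -0.424 in PGC and -0.15 and -0.237 in SC, where fewer controls enter each effect.

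In the 16 class comparisons the log2 ratio of library 1 to library 2 of the exposed group correlated across miRNAs with that of the control group at r from -0.112 to 0.623, with 4 above 0.1 and 2 below -0.1. The 4 are those of F2Sy (0.623 and 0.106 for MEHP in PGC and SC, 0.298 and 0.443 for VZN). Among all pairs of groups r lay above 0.1 in 23 of 66 in PGC and 28 of 66 in SC, so passing 0.1 marks no shared pattern. The highest r of either fraction, 0.623 and 0.443, are among the 4. MEHP and VZN F2Sy libraries gave r = -0.0302 in PGC and -0.0592 in SC. The labels do not say what the numbers share. For the 2 below -0.1, crossed numbers gave 0 calls each. With the replicate number as a block no count of called miRNAs changed (211 for PGC against SC), and camera called 3 lists in place of 1 for VZN PGC F2. The block is a single term shared by all groups. It could not take up a pairing in F2Sy alone, and no such pairing was fitted.

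The limits are 2 libraries per group, with the origin of the replicates not given in the labels, and a table with blank cells. For a single class 16.2% of 2-fold changes were recovered in simulated PGC tables and 29.4% in SC tables, so a 2-fold change in a single class would mostly be missed.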

Other observations

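Both MEHP PGC F2Sy libraries had a higher mean of the X-linked list than the other 22 PGC libraries, with a group mean of 11.15 log2 CPM against 10.39 in control F2Sy. This difference of 0.761 exceeds the SD within groups (0.418), and 2 of the 12 PGC replicate pairs had a gap at least as large. In the same libraries the miR-302-367 list stood at 7.908 against 8.812 in control F2Sy and the let-7 list at 9.502 against 8.729, and the mesenchymal and Dlk1-Dio3 lists, both higher in the somatic fraction, were 0.80 and 0.38 higher than in control F2Sy. These values were picked out after they were seen.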
